A study of Homo sapiens with 4 samples.

How the data were processed

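WI-38 cells are a strain of human fetal lung fibroblasts with a limited lifespan in culture. The labels describe cells at population doubling level 20 that were plated 24 hours before transfection in medium with 20% serum. They were transfected with 50 nM of a control miRNA or of anti-miR-340-5p, an antisense inhibitor (antagomiR) of the microRNA miR-340-5p, and kept for 4 days with the medium changed every 48 hours. Each group had 2 libraries, made from total RNA with an integrity number above 7.0 per the labels.

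The deposited files hold whole-number read counts per Ensembl gene, without normalization, for 57773 gene rows in each library. The submitters' processing notes list STAR, featureCounts 1.4.6-p5, DESeq2 1.26.0 and the genome build hg19, without saying what each did. Strandedness, the treatment of reads with several positions and the annotation release are not given in the sources used here. The labels' protocols describe a small RNA library kit and 36-base single-end reads, whereas protein-coding genes held 71.8% to 75.0% of the counts in these files. The column header of the control files uses the word mimic, and the groups were taken from the sample labels.

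Several properties of the counts bear on their use. Among genes with 1 to 10 counts, 76.9% to 79.0% of values were even, against 50.1% to 50.8% among genes with 1001 to 5000 counts. Such an excess arises when each fragment adds 2 counts, for instance when both ends are counted, which would leave fewer independent fragments than the totals. Its origin was not tested. Copies of the U1 small nuclear RNA gene carried nearly equal counts (RNU1-1 699705 and RNU1-3 699422 in control replicate 1), and WDR74 carried 550743 counts beside 550202 for the RNU2-2P gene that it overlaps. Mitochondrially encoded genes were at 0 counts in all 4 libraries. Members of multigene families, overlapping genes and antisense genes are therefore uncertain.

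Gene names came from a gene name table and GENCODE release 29 by gene ID, which named 39880 of the 57773 rows. Coordinates and 3′ UTR sequences are those of GENCODE release 29 on GRCh38 and were joined to the counts by gene ID alone. The totals were 47454419 and 48164851 counts in the control libraries and 48437514 and 49013280 in the anti-miR-340-5p libraries.

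Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 23636 genes. They were scaled with TMM factors of 0.963 and 0.976 for the controls and 1.04 and 1.02 for the anti-miR-340-5p libraries. The groups were compared with edgeR's quasi-likelihood F test (robust estimation, no covariates, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors (SE) are the size of the log2 fold change divided by the square root of F. Levels are edgeR CPM, counts divided by the TMM-scaled library size, given as mean ± SD. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 8.1%. On simulated counts for this comparison, with 22911 genes tested, the test recovered 84 of 100 genes changed 2-fold and 70 of 100 changed 1.5-fold, with 5 false calls among 159. The changed genes were drawn only from genes above a minimum mean CPM and were far fewer than those called in the data. The simulated counts had no excess of even values, so the test may do less well on the real counts.

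A total of 28 gene lists were fixed before the data were examined, with 548 of 563 entries matched to a gene ID. The 25 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, adjusted over the lists. Another 11 lists were chosen after seeing the data. Genes are named by a rule set at the same time as the fixed lists. It takes LBR, RNF130 and the 3 members of each fixed list with the smallest p past the threshold. It also takes the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol, a mean CPM of at least 5 and no overlap between the groups. It yielded 95 genes, of which the report gives a part, and some are not reported here. Other list members are named as examples chosen after their values were seen.

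For direct targets, the longest annotated 3′ UTR of each gene (at least 30 bases) was searched for CTTTATA, the match to bases 2 to 8 of miR-340-5p. The difference in median log2 fold change between genes with and without the match was ranked among all distinct 7-mers of the same base composition. This exact enumeration of the base orders gives a one-sided p.

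The alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, the replicate number as a block, non-robust estimation, a test against a fold of 1.2, fry, an estimated correlation in camera, other match types and leaving out each library. Protein-coding genes only, library sizes only for the lists, and counts halved and rounded up were alternatives chosen after seeing the data.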

Results

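RNA from WI-38 human fetal lung fibroblasts was profiled 4 days after transfection with 50 nM of a control miRNA (2 libraries) or of anti-miR-340-5p (2 libraries). The series title links miR-340 to suppression of LBR, the lamin B receptor of the inner nuclear membrane, and to chromatin and senescence. The comparison asks which transcripts differ between cells given anti-miR-340-5p and cells given the control miRNA. Neither the degree of inhibition of miR-340-5p nor other effects of the oligonucleotides were measured in these data. The 4 libraries held 47454419 to 49013280 counts, with 31794 to 32506 genes detected. The control libraries correlated at 0.988 and the anti-miR-340-5p libraries at 0.986 (Pearson, across genes, log2 CPM, genes not being independent replicates). The first principal component (64.6% of the variance) separated the groups, and the second (19.5%) separated the anti-miR-340-5p libraries from each other.

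LBR, the gene named in the series title, was at 55.7 ± 4.06 CPM with the control and 66.6 ± 8.61 CPM with anti-miR-340-5p (SD, n = 2 each), a log2 fold change of 0.26 (SE 0.085, edgeR adjusted p = 0.0308). Transcripts of cell division genes rose far more. All 30 measured mitosis genes and 31 of 33 DNA replication genes were higher, and the B-type lamin LMNB1 rose from 5.08 ± 0.344 to 40.7 ± 3.34 CPM. Transcripts of the extracellular matrix fell (24 of 31), with elastin (ELN) decreasing from 47.1 ± 4.26 to 5.86 ± 0.893 CPM. Of p53 target genes, 20 of 25 fell, among them the cell cycle inhibitor CDKN1A (737 ± 18.2 to 479 ± 18.3 CPM).

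The rise of LBR rested on single libraries. Its values were 58.6 and 52.8 CPM in the controls and 60.5 and 72.6 CPM with anti-miR-340-5p. The log2 fold change was 0.19 without control replicate 2 (edgeR adjusted p = 0.3) and 0.12 without anti-miR-340-5p replicate 2 (adjusted p = 0.262). LBR (ENSG00000143815) lies on chromosome 1 from 225401502 to 225428925 on the minus strand (GRCh38). Its 3′ UTR of 1801 bases in transcript ENST00000272163.8 holds 2 matches to bases 2 to 8 of miR-340-5p, of which the one at base 886 of the UTR is a full 8-mer (CTTTATAA). RNF130, whose span on chromosome 5 contains MIR340, was at 16.3 ± 0.0613 and 14.9 ± 1.83 CPM (log2 fold change −0.13, adjusted p = 0.419). The MIR340 hairpin gene itself had 2 and 2 counts in the controls and 0 and 2 with anti-miR-340-5p, too few to compare, and these counts do not measure the mature microRNA.

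**Figure D1:**
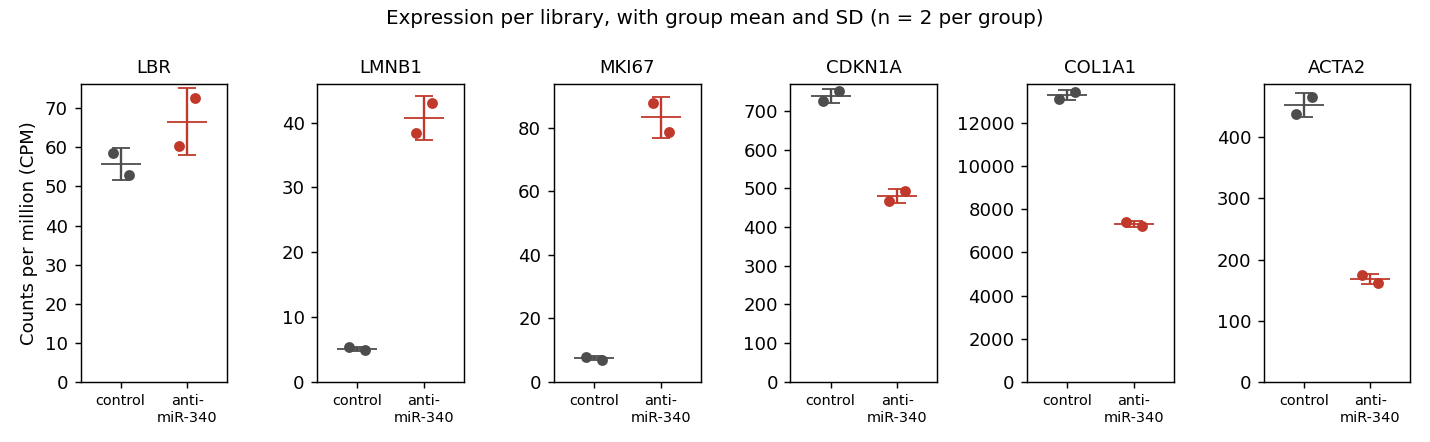
Expression of 6 genes in each library, in CPM on a linear axis from 0, for control (grey) and anti-miR-340-5p (red) libraries, where points are libraries and horizontal lines with bars are the mean and SD (n = 2). LBR differs by 0.26 on the log2 scale with the groups close together. LMNB1 and MKI67 are higher and CDKN1A, COL1A1 and ACTA2 are lower by more than the spread between replicates.

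Of 23636 genes tested, 3479 were higher and 2974 lower with anti-miR-340-5p (edgeR, adjusted over all genes), and 694 and 779 of these changed at least 2-fold. Protein-coding genes made up 2972 of the higher and 2242 of the lower genes, out of 14146 protein-coding genes tested. Counts of list members called are to be read beside these shares. The genes with the largest rises by the naming rule were mitotic kinesin KIF4A (log2 fold change 4.47, SE 0.164), the ribonucleotide reductase subunit RRM2 (4.04, SE 0.094), the spindle protein DLGAP5 (3.92, SE 0.141), linker histone H1-5 (3.83, SE 0.147), CDK1 (3.82, SE 0.156), NDC80 (3.78), HMMR (3.74), CEP55 (3.72), SKA1 (3.62) and TTK (3.61). Those with the largest falls were kinesin KIF26B (−3.32, SE 0.106), the small GTPase RASL11B (−3.26, SE 0.112), ELN (−3.0, SE 0.112), TSPAN11 (−2.86), OLFM2 (−2.83), the phosphodiesterase PDE1A (−2.74), the Hedgehog-binding protein HHIP (−2.63), the glutamate receptor subunit GRIA4 (−2.46), PTCHD4 (−2.38) and the Wnt receptor FZD8 (−2.36). With library sizes only as the scaling, which moved the median gene by 0.089, 4775 genes were higher and 2237 lower, so that 68.1% of calls were higher against 53.9% with TMM. Without control replicate 2 the counts were 2291 and 1789, and without control replicate 1 they were 2460 and 1919.

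**Figure D2:**
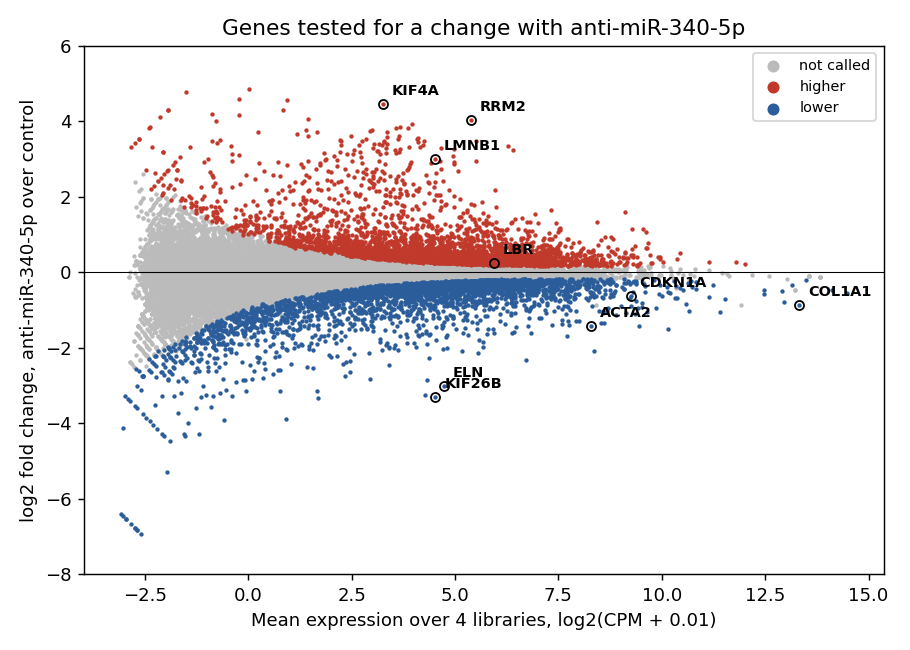
Log2 fold change (anti-miR-340-5p over control) of each tested gene against its mean expression over the 4 libraries, as log2 of CPM plus 0.01, with genes called higher in red, lower in blue and others in grey. A total of 5 genes lie outside the plotted range, and the lines of points at the lower left are genes with 0 counts in the anti-miR-340-5p libraries, whose fitted fold changes depend on the model.

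Genes of the cell division machinery had the largest median rise of the tested lists. All 30 mitosis genes were higher (median log2 fold change 3.26), including topoisomerase TOP2A (14.0 ± 1.47 to 143 ± 12.9 CPM), the proliferation marker MKI67 (7.48 ± 0.667 to 83.4 ± 6.42 CPM) and the cytokinesis protein ANLN (16.1 ± 1.22 to 152 ± 2.90 CPM). The camera call of this list held with an estimated correlation (adjusted p = 2.09e-198 preset, adjusted p = 0.0444 with an estimated correlation). It was the only list for which that was so. DNA replication genes rose in 31 of 33 (median 1.75, camera adjusted p = 4.48e-65, and adjusted p = 0.0734 with an estimated correlation). DTL was at 3.25 and the helicase subunit MCM4 at 1.95, while CCNE1 (−0.16) and RFC5 (0.10) did not pass. DNA damage repair genes rose in 22 of 27 and none fell (median 0.88, adjusted p = 9.04e-25, and adjusted p = 0.0734 with an estimated correlation), with FANCD2 at 2.56 and BRCA1 at 2.43. Adjusted over the list alone, 23 repair genes were higher and 1 lower, and the mitosis and replication counts did not change. Replication-dependent histones rose in 12 of 14 measured (median 1.19, adjusted p = 9.76e-26, and adjusted p = 0.0734 with an estimated correlation, same counts adjusted over the list alone). H2AC11 was at 2.10 and H4C8 at 1.11, although reads of these near-identical genes are hard to assign. PRC1 (3.28) and its antisense gene PRC1-AS1 (3.59) both rose, and whether reads were counted by strand was not tested.

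Nuclear lamina and envelope genes were higher in 9 of 17 and lower in 3 (median 0.21, camera adjusted p = 3.89e-05, and adjusted p = 0.143 with an estimated correlation), with the same counts adjusted over the list alone. LMNB1 (3.0, SE 0.108), the lamina-associated TMPO (2.19, SE 0.078) and LMNB2 (0.89, SE 0.068) had the smallest p. LMNA rose by 0.21, and the nesprin SYNE1 (−0.71), LEMD2 (−0.32) and TOR1AIP1 (−0.24) fell. Without control replicate 2 only 1 lamina gene was lower. Of 22 heterochromatin and chromatin repression genes, 12 were higher and 3 lower (median 0.30, camera adjusted p = 0.000686, and adjusted p = 0.145 with an estimated correlation), or 12 and 4 adjusted over the list alone. HMGB2 (2.21), the Polycomb methyltransferase EZH2 (1.47) and the DNA methyltransferase DNMT1 (1.11) rose. The histone H3 methyltransferases SUV39H2 (1.03) and SUV39H1 (0.65) also rose, and ATRX (−0.74) and HMGA2 (−0.49) were among those that fell.

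**Figure D3:**
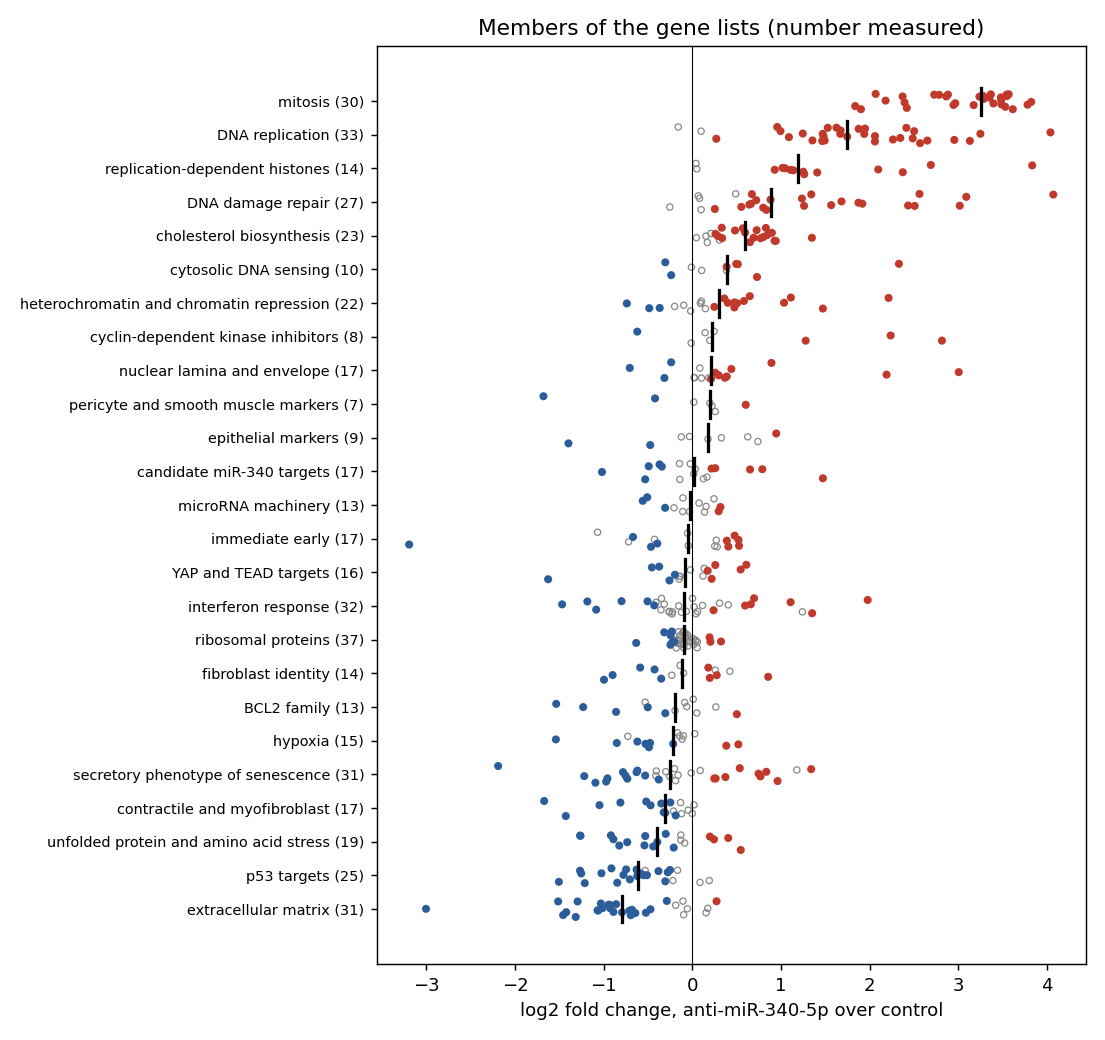
Log2 fold change (anti-miR-340-5p over control) of each measured member of the 25 tested gene lists, with the number measured beside each name, filled points for genes called higher (red) or lower (blue), open points for genes not called and a black line at the median. Medians run from 3.26 for mitosis to −0.79 for the extracellular matrix.

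Genes tied to senescence moved in different directions. p53 targets were lower in 20 of 25 and higher in none (median −0.61, camera adjusted p = 1.82e-18, and adjusted p = 0.0734 with an estimated correlation), or 23 lower adjusted over the list alone. BTG2 was at −1.51, SESN2 at −1.27 and ZMAT3 at −1.03. Among 8 cyclin-dependent kinase inhibitors, 3 were higher and 1 lower (same counts adjusted over the list alone), and the members did not move together. CDKN1A fell (−0.62, SE 0.060), and CDKN3 (2.81), CDKN2C (2.23) and CDKN2D (1.28) rose. CDKN2A (0.24) and CDKN2B (−0.01) of this list did not pass. Its camera call (adjusted p = 0.0348, and adjusted p = 0.445 with an estimated correlation) was lost without control replicate 1 (0.0574), control replicate 2 (0.0884) or anti-miR-340-5p replicate 2 (0.118), and with counts halved (0.0575). It was called in 4 of the 10 settings tried, and 5 inhibitors were higher with library sizes only. Of 31 genes of the secretory phenotype of senescence, 9 were higher and 12 lower (same counts adjusted over the list alone). The call of a lower list (adjusted p = 0.0348, and adjusted p = 0.445 with an estimated correlation) was lost without control replicate 1 (0.0574), control replicate 2 (0.195) or anti-miR-340-5p replicate 1 (0.0528) and with library sizes only (0.0655), and held in 6 of 10 settings. INHBA (−1.22), the matrix protease MMP14 (−1.09) and IGFBP3 (−0.96) fell. The chemokines CXCL8 (1.34) and CCL2 (0.83) and the collagenase MMP1 (0.96) rose, and IL6 was at −0.19 without passing. In the BCL2 family, 1 gene was higher and 5 lower of 13 (2 and 6 adjusted over the list alone; camera adjusted p = 0.0506, and 0.0389 without control replicate 2, where 2 were higher). BMF was at −1.54, BCL2 at −1.23 and BCL2L2 at 0.50.

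Innate sensing genes went both ways. Interferon response genes were higher in 7 and lower in 6 of 32 (camera adjusted p = 0.983), or 7 and 7 adjusted over the list alone. Across all 14146 protein-coding genes tested, 2972 were higher and 2242 lower, so these counts do not set the interferon list apart. OAS3 (1.98) and STAT2 (0.66) were higher and TRIM22 (−0.80) lower. Only 3 were higher without control replicate 2. Of 10 genes of cytosolic DNA sensing, 5 were higher and 2 lower (same counts adjusted over the list alone). The smallest p were those of RNASEH2A (2.33), the catalytic subunit of an RNase H complex, SAMHD1 (0.73) and IRF3 (0.49). CGAS (0.51) also passed, while STING1 (−0.01) did not. The camera call of this list as higher (adjusted p = 0.0348, and adjusted p = 0.411 with an estimated correlation) was lost without control replicate 2 (0.0629), without anti-miR-340-5p replicate 2 (0.0649) and with counts halved (0.0575), and held in 5 of 10 settings. Without control replicate 2, 3 were higher and 0 lower, without control replicate 1, 0 were lower, and without anti-miR-340-5p replicate 2, 3 were higher. With library sizes only, 6 were higher and 0 lower.

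Extracellular matrix genes fell in 24 of 31 and rose in 1, LOXL1 at 0.27 (median −0.79, camera adjusted p = 4.45e-40, and adjusted p = 0.143 with an estimated correlation), or 25 and 2 adjusted over the list alone. The basement membrane collagen COL4A1 fell from 1671 ± 69.5 to 585 ± 39.97 CPM (−1.51, SE 0.066). THBS2 was at −1.46, COL1A1 at −0.86 and COL1A2 at −0.79, while fibronectin FN1 (−0.19) did not pass. No matrix gene was higher without control replicate 1 or anti-miR-340-5p replicate 1, and 3 were without anti-miR-340-5p replicate 2. Contractile and myofibroblast genes fell in 11 of 17 and none rose (median −0.31, adjusted p = 6.83e-09, and adjusted p = 0.175 with an estimated correlation, same counts adjusted over the list alone). Smooth muscle actin ACTA2 fell from 452 ± 19.8 to 168 ± 8.56 CPM, with TPM1 at −1.05 and the collagen-binding integrin ITGA11 at −1.67. Without control replicate 2, 7 contractile genes fell. The antisense genes ACTA2-AS1 (−1.39) and VCAN-AS1 (−1.50) fell with ACTA2 (−1.43) and VCAN (−1.42), and here too counting by strand was not tested.

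Cholesterol biosynthesis genes rose in 18 of 23 and none fell (median 0.59, camera adjusted p = 6.05e-11, and adjusted p = 0.0734 with an estimated correlation), or 19 adjusted over the list alone. LSS, the lanosterol synthase, rose from 49.6 ± 3.74 to 92.2 ± 0.878 CPM (0.90, SE 0.073), and INSIG1 was at 0.93. LBR also encodes a sterol reductase, and TM7SF2, which encodes another sterol C14 reductase, rose by 0.94. Genes of the unfolded protein and amino acid stress list were lower in 12 of 19 and higher in 4 (median −0.40, adjusted p = 4.16e-06, and adjusted p = 0.124 with an estimated correlation, same counts adjusted over the list alone). The members that fell included the serine and asparagine synthesis genes PSAT1 (−1.26) and ASNS (−0.92), whereas the endoplasmic reticulum chaperones HSPA5 (0.20) and HSP90B1 (0.40) rose. Only 2 were higher without control replicate 1. Hypoxia genes were lower in 7 and higher in 2 of 15 (adjusted p = 0.0199, and adjusted p = 0.286 with an estimated correlation), or 8 and 2 adjusted over the list alone. NDRG1 was at −0.85, VEGFA at −0.62 and SLC2A1 at −0.48.

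The other lists had members going both ways and no camera call. Members called in both directions are also found among protein-coding genes at large (2972 higher and 2242 lower of 14146). YAP and TEAD targets were higher in 5 and lower in 5 of 16 (adjusted p = 0.981; 5 and 6 adjusted over the list alone; 2 and 3 without control replicate 1, 3 and 3 without control replicate 2). CCN2 was at 0.61 and F3 at −0.46. Immediate early genes were higher in 5 and lower in 4 of 17 (adjusted p = 0.983; 6 and 5 adjusted over the list alone). EGR1 was at −0.67 and FOSL1 at 0.52, and 2 were lower without either control library and 3 higher without anti-miR-340-5p replicate 2. Genes of the microRNA machinery were higher in 2 and lower in 3 of 13 (adjusted p = 0.655, same counts adjusted over the list alone), with DICER1 (−0.51) and AGO3 (−0.56) lower. In that list 1 was higher without control replicate 2, and 5 were higher and 3 lower with library sizes only. Ribosomal protein genes were higher in 3 and lower in 7 of 37 (adjusted p = 0.0838, and adjusted p = 0.696 with an estimated correlation; 3 and 10 adjusted over the list alone), with RPS19 at −0.63, and many have near-identical pseudogenes. That list was called lower without control replicate 2 (0.00684; 0 higher and 4 lower) and without anti-miR-340-5p replicate 1 (0.0252; 16 lower), and had 1 higher and 1 lower without control replicate 1. With library sizes only, 3 were higher and 2 lower (adjusted p = 0.405). Mitochondrially encoded genes were at 0 counts in all libraries and were not tested.

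Markers of cell identity moved in both directions. Fibroblast identity genes were higher in 4 and lower in 5 of 14 (camera adjusted p = 0.15; 4 and 6 adjusted over the list alone; 1 higher without either control library). TCF21 was at 0.85, P4HA2 at −0.90 and FAP at −0.59. Of 7 pericyte and smooth muscle markers, 1 was higher and 2 lower (adjusted p = 0.449, same counts adjusted over the list alone), with RGS5 at −1.68, NOTCH3 at −0.42 and CSPG4 at 0.60. Epithelial markers were higher in 1 and lower in 2 of 9 (adjusted p = 0.981; 2 and 2 adjusted over the list alone), with KRT19 at 0.94 and KRT8 at −0.48. KRT7 (87, 27, 19 and 28 counts) was no longer called without control replicate 1 (−0.29). Of 3 endothelial and 4 immune markers measured, too few to test as lists, TEK rose by 0.23 (not called without either control library) and CD68 by 0.61. PTPRC had 13 and 14 counts in the controls and 0 in both anti-miR-340-5p libraries, and was too low to be tested with counts halved.

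Genes previously proposed as miR-340 targets, compiled from background knowledge, were higher in 5 and lower in 5 of 17 (camera adjusted p = 0.981), or 6 and 5 adjusted over the list alone. LBR, PLAT (0.79) and EZH2 (1.47) were higher and CDK6 (−1.02) lower. Without control replicate 2, 3 were higher. Across 13810 genes with a searched 3′ UTR, the 2538 with the 7-mer match had a median log2 fold change of 0.016, against 0.027 for genes without it. The difference was −0.012 (bootstrap over genes, 95% interval −0.029 to 0.010). The libraries were held fixed, so the interval leaves out variation between samples. The difference was exceeded by 20 of the 104 other 7-mers of the same composition (one-sided p = 0.2, exact enumeration). Genes with the 8-mer differed by −0.030 from those without it, a difference exceeded by 72 of the 104 others. The difference was 0.006 without anti-miR-340-5p replicate 1 and −0.029 without anti-miR-340-5p replicate 2, and neither passed.

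**Figure D4:**
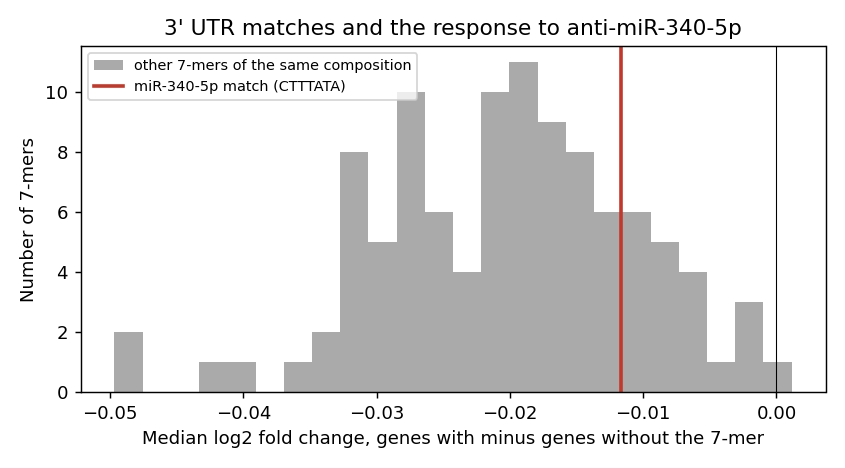
Number of 7-mers (vertical axis) by the difference in median log2 fold change between genes with and without the 7-mer in the 3′ UTR (horizontal axis), for the other 7-mers of the same base composition (grey) and the match to miR-340-5p (red line). The match lies at −0.012, inside the range of the others.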

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

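Of the 6453 genes called, 0 had a log2 fold change of the opposite sign in any alternative fit that tested them, called there or not. This outcome was nearly fixed in advance and is no separate support. The groups did not overlap for any called gene (3479 higher and 2974 lower), and every fit reused the same libraries. The number that kept their call fell to 3224 with glmTreat. Against a fold of 1.2 rather than 1, edgeR's glmTreat called 1698 genes higher and 1526 lower, and LBR, with the same log2 fold change of 0.26, no longer passed (adjusted p = 0.646), because that test asks for a larger change. Leaving out each library in turn gave 2291 to 3921 genes higher, 1789 to 3428 lower, a log2 fold change of LBR from 0.12 to 0.39 and a seed-match difference from −0.029 to 0.006, with 7 to 9 lists called higher and 5 to 7 lower. In these fits the lone library was assumed to vary like the other group. The anti-miR-340-5p libraries differed more from each other than the controls did (chi-square of the counts per degree of freedom 17.05 and 6.24). Whether this caused the differences between these fits was not tested. With an estimated correlation, 1 list was called higher and 0 lower, against 9 and 6 with the preset value. A larger correlation does not account for every lost call. The estimate was below the preset 0.01 for p53 targets (−0.005) and cholesterol biosynthesis (−0.027), and above it for the extracellular matrix (0.355). Losing the call with this option therefore does not by itself show that the members of a list were correlated. Fry, which tests whether a list moves without comparing it with other genes, called 9 higher and 7 lower. It added the BCL2 family (fry adjusted p = 0.0226) and the microRNA machinery (0.0106) as lower and dropped the secretory phenotype of senescence (0.0762). The labels number the replicates of both groups alike, but same-numbered libraries did not deviate together (correlation −0.011 over all genes). No shared effect was visible, although this cannot tell whether the replicates were handled in pairs. The replicate block gave 3576 genes higher, 3157 lower and 0.25 for LBR. Protein-coding genes only (2994 higher, 2857 lower) and counts halved (3503 and 3168, LBR 0.25), both chosen after seeing the data, stayed within 1.5 times the counts. LBR aside, of 1405 values of the named genes under the alternatives, 1390 kept their direction and side of the threshold, 14 no longer passed (KRT7, TEK, RPLP2, RPL18, KRT8 and TNRC6B) and 1, PTPRC with DESeq2, had no adjusted p. Low counts limit what could be seen, since most of their values were even and may stand for fewer fragments.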

Other observations

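The 11 gene lists described first were chosen after seeing the data, and so were the tests of library scaling, of a swapped library, of power from other starting values and of pseudogenes by the direction of their parents. Genes induced by TGF-beta were lower in 11 of 14 and higher in 2 (median log2 fold change −1.13, camera adjusted p = 8.78e-24, and adjusted p = 0.144 with an estimated correlation). They included the metalloprotease ADAM19 (−2.09), PMEPA1 (−1.23) and the inhibitory SMAD7 (−1.12), while CCN2 (0.61) and IL11 (0.48) rose. Genes of collagen folding and secretion were lower in 13 of 19 and higher in 1 (adjusted p = 1.48e-08, and adjusted p = 0.15 with an estimated correlation), including the procollagen peptidase ADAMTS2 (−1.36) and the collagen chaperone SERPINH1 (−0.47), with FKBP10 (0.32) higher. Of 11 Hedgehog pathway genes 5 were lower and 0 higher (adjusted p = 6.55e-05, and adjusted p = 0.145 with an estimated correlation), with the receptor PTCH1 at −0.85 and the co-receptor BOC at −2.14, while GLI1 (−0.19) did not pass. Of 11 Notch pathway genes 5 were lower and 0 higher, with the ligand JAG1 at −1.15 and HES1 at −0.91 (adjusted p = 0.0197, and adjusted p = 0.16 with an estimated correlation). Lysosomal genes were lower in 12 of 25 and higher in 2 (adjusted p = 0.0188, and adjusted p = 0.274 with an estimated correlation), with the cathepsin CTSK at −0.57 and the senescence-associated beta-galactosidase gene GLB1 at −0.23.

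Cohesin and condensin genes were higher in 9 of 13 and lower in none (median 0.99, camera adjusted p = 5.59e-22, and adjusted p = 0.142 with an estimated correlation). They included the condensin subunits NCAPH (3.15) and NCAPD3 (0.52) and the cohesin subunits SMC1A (1.04) and RAD21 (0.59). The condensin gene NCAPH2 (0.29) and the cohesin genes SMC3 (0.11), STAG2 (0.04) and STAG1 (−0.001) did not pass. Nuclear pore genes were higher in 15 of 22 and lower in 0 (median 0.34, adjusted p = 1.81e-05, and adjusted p = 0.144 with an estimated correlation), led by NDC1 (1.47). Nucleotide synthesis genes were higher in 12 of 17 and lower in 2 (adjusted p = 4.73e-07, and adjusted p = 0.145 with an estimated correlation), with thymidine kinase TK1 at 2.34, while the mitochondrial folate enzymes MTHFD2 and SHMT2 fell by 0.77 and 0.21. Ribosome biogenesis genes were higher in 10 of 19 and lower in 1 (adjusted p = 0.00186, and adjusted p = 0.15 with an estimated correlation), with NPM1 at 0.47 and NOP16 at −0.40. Glycolysis genes were higher in 8 of 15 and lower in 1 (adjusted p = 0.0128, and adjusted p = 0.15 with an estimated correlation), with PKM at 0.50 and HK2, the largest change in size, at −0.57. Autophagy genes went both ways, with 6 higher and 3 lower of 17 (adjusted p = 0.305).

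The rise of cell cycle genes was set against 3 technical explanations. Under 3 other scalings the median log2 fold change of the mitosis list was at least 3.23, so none of these scalings accounts for it. This outcome was nearly fixed in advance, since library sizes only moved the median gene by just 0.089. Genes outside the lists, matched on GC content, length and expression to the mitosis and replication genes, had a median of 0.046 (1157 genes), against 2.42 for the 63 cell cycle genes. The gap between the groups was 18.5 times the larger difference within a group, so no single library lay with the other group. The share of dividing cells, a difference in culture density between the groups and a full exchange of the group labels were not tested.

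Genes with a miR-340-5p match did not rise as a group, which may mean too little power, or a response of few targets. How far miR-340-5p was inhibited was not measured in these data. With 0.05 added to every gene with the match it ranked 1 among all 7-mers of its composition, but its observed value fixed that outcome. With 0.05 added to the genes of each of the 104 other 7-mers in turn, 97.1% reached the first 5. With 0.02 added 36.5% did, and with 0.01 added 17.3% did, so power was low for uniform shifts of these sizes. The share of matched genes called higher, 22.3%, ranked 44, with 43 of the 104 other 7-mers at least as high, so an excess of rising targets was not visible either. A handful of targets, effects on protein alone and the isoforms these cells use were not tested.

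Processed pseudogenes were lower more often than higher (162 and 43 of 2230 tested). Reads shared with parent genes may add to this, since across 1623 pseudogenes with a tested parent, the log2 fold changes correlated with those of 720 parents (Spearman rho 0.332, and 0.321 with 1 pseudogene per parent, permutation p = 1e-04, the smallest that 10000 permutations can give, across genes, which are not independent). Where the parent's log2 fold change was above 0, called-lower pseudogenes were 0.964 times as many as called-higher ones (27 and 28), and below 0 there were 101 and 3. Whether shared reads account for the whole excess cannot be told from these counts. More of the pseudogenes had a parent called higher (495) than a parent called lower (226). The 71 called lower whose parent was not called do not decide it, because such a parent can still have a log2 fold change below 0. Regulation of the pseudogenes themselves was not tested.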
